A study of Mus musculus with 12 samples.

How the data were processed

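Bulk RNA of whole embryonic mouse hearts was sequenced in 12 libraries, 1 per embryo: 3 wild-type (WT) and 3 Ino80-disrupted (KO) hearts at embryonic day 13.5 (E13.5), and as many of each at E14.5. Per the labels, the disruption was endothelial and used Tie2, libraries were made with a NEBNext Ultra kit, and the molecule was total RNA, with a protocol of mRNA extraction from whole hearts. Per the labels, all 6 E13.5 embryos came from litter 1, while the E14.5 embryos came from litter 2 (WT replicates 7 and 8, KO replicates 2 and 4) and litter 3 (WT replicate 7.2, KO replicate 1). Stage is therefore confounded with litter, while each litter held both genotypes. The strain and the deleted part of Ino80 were not given in the sources used here.

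The deposited table holds raw counts per gene symbol, whole numbers with no normalization, in 45664 rows. Per the submitters' processing notes, the tools were STAR 2.5.3a, featureCounts, DESeq2 and DESeq with genome build GRCm38, listed without role or order. Counting settings (strand, multi-mapping reads, fragments or reads), the annotation release and any filter were not given in the sources used here. All rows of mitochondrially encoded genes are 0 in all 12 libraries, so that list was not tested. Symbols that a spreadsheet had turned into dates took 27 rows, 2 of them duplicates, and no gene of the fixed lists was read from them. Libraries totalled 46556032 to 182545647 counts. No 2 libraries of the same group were copies of one another in a check of their counts. Pairs of libraries from different groups were not checked.

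Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on the 4 groups left 20691 genes, libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries (8 residual degrees of freedom, common biological coefficient of variation 17.1%). Two-sided quasi-likelihood F-tests compared KO with WT at each stage and averaged over the stages, the KO effect at E14.5 minus that at E13.5 (the interaction), and E14.5 with E13.5 in each genotype. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. They measure the spread between embryos, not the counting error of 1 library. Errors of the edgeR log2 fold changes are approximate standard errors (SE). Each is the absolute log2 fold change divided by the square root of its F statistic. Levels are library-scaled counts (CPM of edgeR) as mean ± standard deviation (SD) of 3 embryos. Coordinates are those of GENCODE M21 on GRCm38, matched by symbol for 20006 of the tested genes (96.7%).

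Of 36 fixed gene lists for cell types, pathways and processes (589 genes, 548 of them tested), 34 were tested with camera of limma 3.58.1, which asks in a two-sided test whether a list moved relative to the other genes. The preset inter-gene correlation was 0.01, the minimum was 3 tested members, and p-values were adjusted over the 34 lists. Each call is given beside camera with a correlation estimated per list. Mitochondrially encoded and sex-linked genes made up the lists left out. A score is the mean log2 CPM of a list in 1 embryo; scores were compared by two-sided exact permutation tests, in which 3 embryos against 3 cannot go below p = 0.1.

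Named genes followed a rule: Ino80; the 8 highest and 8 lowest fold changes among called genes with a mean of at least 1 CPM and no overlap between the groups, leaving out clone-based and predicted symbols and sex-linked genes; for each called list, or list with 3 called members, the 3 members with the smallest p in its direction and 1 in the other; a fixed panel of 15 endothelial, myocardial and stress genes at each stage; 5 genes each way for the interaction; and in KO, the genes named for the stage comparison in WT. The fixed panel includes the epicardial gene Wt1, the cell cycle gene E2f1 and the globin gene Hbb-bs. Comparisons, lists, this rule and all but 2 of the alternatives were chosen before the data were examined.

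Alternatives were: DESeq2 1.42.0 (Wald test), RLE size factors, no low-count filter, only the libraries compared, litter as a block, Y-linked expression or erythroid expression as a covariate, and leaving out each library in turn. For lists, camera with an estimated correlation and fry were added to these. Leaving out litter 3, and leaving out E13.5 KO replicate 5 with E14.5 KO replicate 2, were added after seeing the data. Litter pairing comes from the labels. Between WT and KO embryos at E14.5, residuals had a mean correlation across genes of -0.0449 within litters, against 0.056 between litters. This measure did not show the pairing, and genes are not independent replicates. Within each genotype, however, litter 3 stood apart in the check of counts. Its chi-square per degree of freedom was 18.4 between WT replicates 8 and 7, against 41.8 and 43.7 with WT replicate 7.2. Between KO replicates 2 and 4 it was 49.4, against 152 and 131 with KO replicate 1. The block adds 1 term, litter 3 against litter 2. It cannot adjust KO against WT at E13.5, where all embryos are of litter 1. In the stage comparisons it sets litter 2 against litter 1, so stage stays confounded with litter.

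The fit was tested on simulated data with these libraries' sizes and spread. The changed genes were drawn from genes with a mean of at least 1 CPM that were in none of the fixed lists. The shares recovered therefore do not cover genes at lower levels or the genes of the lists. Of 67 genes changed by 2-fold, 79.1% were recovered at E13.5, 86.6% at E14.5, 95.5% averaged, 73.1% for the interaction, 83.6% for stage in WT and 85.1% for stage in KO. At 1.5-fold the shares were 55.2%, 59.7%, 71.6%, 29.9%, 49.3% and 58.2%. Between 6 and 14 unchanged genes were called per comparison. Camera recovered an 18-gene list shifted by 1.5-fold in each comparison and called 0 of the other 33 lists. With an estimated correlation it missed the shifted list for stage in WT (adjusted p = 0.101) and recovered it in the other comparisons. The simulated genes were drawn independently of one another. The 0 therefore does not show how often camera calls unchanged lists whose members are correlated.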

Results

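The first question was how the 12 hearts related to one another before any test. Stage separated them on the first principal component (24.2% of the variance), on which E13.5 hearts lay between -56.9 and -10.2 and E14.5 hearts between 9.37 and 43.1. On the second component (18.7%), all KO hearts lay below all WT hearts of their stage. At E13.5 they lay between -58.2 and -14.3, against 7.24 to 33.3 in WT. At E14.5 they lay between -38.2 and 7.26, against 14.8 to 29.3 in WT. Of these KO hearts 2 stood apart, E13.5 KO replicate 5 at -58.2 and E14.5 KO replicate 2 at -38.2. The same hearts had the lowest mean log2 CPM of macrophage and leukocyte genes, -0.617 and 0.314. The 6 WT hearts lay between 2.40 and 2.67 on that scale. Globin transcripts made up 0.491% to 1.77% of counts in 11 libraries and 3.98% in E14.5 KO replicate 1. The deepest library held 182545647 counts (E13.5 WT replicate 1) and the shallowest 46556032 (E14.5 WT replicate 8).

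Ino80, the catalytic subunit of the INO80 chromatin remodeller and the target of the disruption (chromosome 2, 119373042 to 119477687), was read in every library. At E13.5 its level was 36.6, 33.8 and 30.7 CPM in WT replicates 1, 4 and 2, and 29.6 CPM in each of KO replicates 3, 5 and 7. At E14.5 it was 33.9, 31.4 and 30.8 CPM in WT replicates 8, 7 and 7.2, and 27.0, 29.5 and 31.9 CPM in KO replicates 2, 4 and 1. The group means were 33.7 ± 2.92 against 29.6 ± 0.0252 CPM at E13.5 and 32.0 ± 1.61 against 29.5 ± 2.45 CPM at E14.5. The log2 fold change was -0.19 ± 0.08 at E13.5 (adjusted p = 0.451), -0.12 ± 0.08 at E14.5 (0.73) and -0.15 ± 0.06 averaged over the stages (0.22), so no difference was detectable with edgeR at this depth and number of embryos. The count covers the whole gene, the deleted part is not given in the sources used here, and whole hearts hold many cells outside the Tie2 lineage. Of the 15 INO80 complex subunits, 0 passed over all genes and 0 adjusted over the list alone in the KO comparisons. The list was not called at E13.5 (median log2 fold change 0.00, adjusted p = 0.897), at E14.5 (-0.01, 0.968) or averaged (-0.02, 0.972). With stage, camera did not call it in WT (-0.07, 0.0661) or in KO (-0.07, 0.0708), while fry did in both (0.0171 and 0.0151), with 2 and 3 of 15 members above 0 and, adjusted over the list alone, 0 and 2 down.

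What set KO hearts apart from WT hearts was asked most sensitively with the KO effect averaged over both stages, 6 KO against 6 WT embryos. Among the genes that rose were Bst2, Eda2r, Mlkl and Cdkn1a. Bst2, an interferon-induced protein that tethers budding virus particles (chromosome 8, 71534255 to 71537456), rose by 1.36 ± 0.17 on the log2 scale (adjusted p = 0.00446), from 8.75 ± 0.698 to 22.5 ± 5.64 CPM at E13.5 and from 9.49 to 24.2 CPM at E14.5. Eda2r, a tumour necrosis factor receptor family member and p53 target (chromosome X, 97333840 to 97377216), rose by 1.59 ± 0.15 (0.000609), and Mlkl, the executioner of necroptosis, by 1.43 ± 0.16 (0.000683). Cdkn1a, the p53-induced inhibitor of cell cycle kinases (chromosome 17, 29090976 to 29100727), rose by 0.82 ± 0.13 (0.0134), from 21.9 to 39.6 CPM at E13.5 and from 28.1 to 48.8 CPM at E14.5. Among genes that fell were Cpa3, a carboxypeptidase of mast cell granules, Pecam1, an adhesion molecule of endothelial junctions, and Mfng and Lfng, the fringe enzymes that modify Notch receptors.

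Cpa3 (chromosome 3, 20215620 to 20242181) fell by 2.65 ± 0.27 (adjusted p = 0.000519), from 1.76 to 0.280 CPM at E13.5 and from 4.12 to 0.630 CPM at E14.5. Pecam1 (chromosome 11, 106654217 to 106750628) fell by 0.47 ± 0.05 (0.000785), Mfng by 0.61 ± 0.10 (0.00983) and Lfng by 0.62 ± 0.11 (0.0127). The endocardial gene Cytl1 fell by 1.79 ± 0.27 (0.00873). Pan-endothelial genes (median 0.09, 16 of 24 above 0, camera adjusted p = 0.228) and endocardial genes (0.17, 9 of 12 above 0, 0.295) were not called as lists, and most of their members lay on the other side from Pecam1 and Cytl1. Among secreted factors, the activin subunit gene Inhbb rose by 1.08 ± 0.17 (0.01) and the growth factor gene Igf1 by 0.41 ± 0.07 (0.0161), while the basement membrane collagen gene Col15a1 fell by 0.94 ± 0.15 (0.0163). In the quasi-likelihood test 293 of 20691 genes changed, 172 up and 121 down. The genes named in this and the preceding paragraph kept their calls when any 1 library was left out. With E13.5 KO replicate 5 and E14.5 KO replicate 2 both left out, Col15a1 (0.0628), Igf1 (0.0631), Inhbb (0.0628), Lfng (0.0777) and Mfng (0.0598) no longer passed, and with litter 3 left out Cdkn1a did not (0.051). The count rested on single libraries more than these genes did: it was 151 without E13.5 WT replicate 1, 125 without WT replicate 4, 163 without KO replicate 3, 145 without KO replicate 5 and 162 without KO replicate 7. Without an E14.5 library it was 166 (KO replicate 2), 190 (WT replicate 7), 444 (KO replicate 4) and 483 (KO replicate 1). It was 63 without E13.5 KO replicate 5 and E14.5 KO replicate 2, and DESeq2 called 933.

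**Figure D1:**
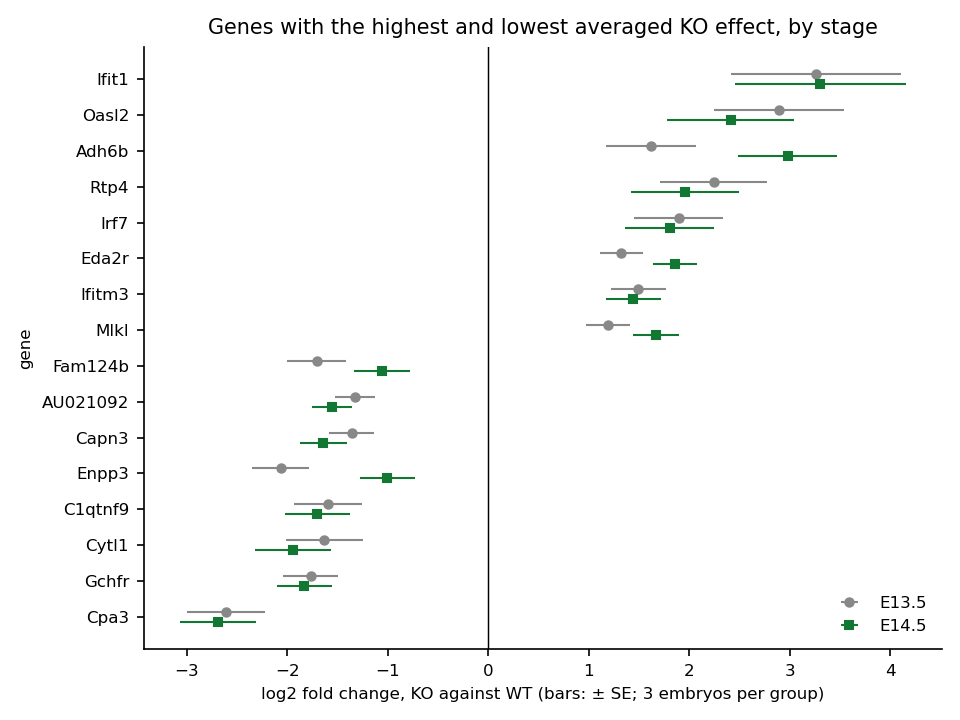
KO effect on 16 named genes at E13.5 (grey circles) and E14.5 (green squares). The x axis is the log2 fold change of KO over WT, bars are ± SE of the edgeR fit with 3 embryos per group, and values right of 0 are higher in KO.

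By gene groups, the interferon response moved furthest in the averaged comparison. Of its 18 measured members 17 lay above 0, with a median log2 fold change of 1.41 (camera adjusted p = 9.91e-25; adjusted p = 0.146 with an estimated correlation); 9 rose over all genes and 16 adjusted over the list alone. Ifitm3, a blocker of virus entry, rose by 1.47 ± 0.19 (adjusted p = 0.00639) and Irf7, a transcription factor that induces interferon genes, by 1.85 ± 0.31 (0.0134). The p53 targets and apoptosis list rose less (median 0.24, 18 of 20 above 0, 1.54e-12; adjusted p = 0.146 with an estimated correlation). Eda2r, Cdkn1a and Zmat3 (0.49 ± 0.08, 0.0106; 0.0581 without E13.5 KO replicate 5 and E14.5 KO replicate 2) were among its 4 members that rose over all genes, against 11 up and 2 down adjusted over the list alone. Hypoxia response genes (median 0.25, 20 of 23 above 0, 6.75e-08; adjusted p = 0.414 with an estimated correlation) included the collagen prolyl hydroxylase gene P4ha2, which rose by 0.47 ± 0.09 (0.0184), and 8 members passed adjusted over the list alone. P4ha2 lost its call without E13.5 WT replicate 4 (0.0517), E13.5 KO replicate 5 (0.0528), E13.5 KO replicate 5 with E14.5 KO replicate 2 (0.117) or litter 3 (0.0656). E13.5 KO replicate 5 and E14.5 KO replicate 2, which stood apart on the second component, had the highest scores of their stages for the p53 list (4.70 and 4.95) and for hypoxia response (5.42 and 5.70). The other KO embryos also lay above all WT embryos of their stage for p53, while for hypoxia at E13.5 they lay within the WT range. Without those 2 libraries both lists kept their averaged calls, with medians of 0.19 for p53 and 0.15 for hypoxia response. Glycolysis genes had a median of 0.19 with 16 of 17 above 0 (3.22e-07; adjusted p = 0.346 with an estimated correlation): 0 members passed over all genes and 7 rose adjusted over the list alone.

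Lower in KO hearts were markers of macrophages and leukocytes, with a median of -0.85 and 17 of 18 members below 0 (camera adjusted p = 4.71e-07; adjusted p = 0.483 with an estimated correlation). None of its members passed, over all genes or adjusted over the list alone, and the list's level varied widely between KO embryos. Fatty acid oxidation genes (median -0.13, 24 of 26 below 0, 5.07e-06; adjusted p = 0.477 with an estimated correlation) and nuclear-encoded respiratory chain genes (median -0.09, 28 of 29 below 0, 0.000318; adjusted p = 0.696 with an estimated correlation) were slightly lower as groups, with 0 members past the test over all genes. With litter as a block, Eci1 (-0.22, 0.0293 against 0.144) and Ppargc1a (-0.25, 0.0293 against 0.110) of the former passed. Coronary arterial endothelial genes had a median of -0.11 with 1 of 17 above 0 (5.19e-05; adjusted p = 0.236 with an estimated correlation), and 3 fell over all genes against 5 down and 1 up adjusted over the list alone. Notch signalling genes had a median of -0.10 with 4 of 16 above 0 (0.00209; adjusted p = 0.236 with an estimated correlation), and 3 fell over all genes, Mfng, Lfng and Jag2, against 4 down and 1 up adjusted over the list alone. Jag2, a Notch ligand, fell by 0.40 but kept its call in 4 of 12 fits with 1 library left out (highest adjusted p 0.0856). These 9 lists kept their calls without any 1 library. At E14.5 alone, however, the macrophage (-0.13, 0.227), coronary arterial (-0.06, 0.103) and Notch (-0.05, 0.253) lists were not called. At fry's two-sided test, 5 lists passed: interferon (0.0358), p53 (0.0155), coronary arterial (0.0411), Notch (0.0411) and endothelial-to-myocardial signals (0.0358).

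Of the 34 lists, 15 were called in the averaged comparison (8 up, 7 down) and 0 with an estimated correlation, where the smallest adjusted p was 0.146. The other 6 called lists lost their calls without single libraries. Endothelial-to-myocardial signals (median 0.19, 0.0256) lost it without E13.5 WT replicate 2 (0.0863), E14.5 WT replicate 7.2 (0.0695) or E14.5 KO replicate 1 (0.119), and immediate-early genes (0.12, 0.00536) without E14.5 KO replicate 1 (0.0841). The liver list (-0.41, 0.0105) lost it without E14.5 KO replicate 4 (0.0575). Integrated stress response genes (0.10, 0.035) lost it without E13.5 WT replicate 2 (0.0649), E14.5 KO replicate 2 (0.154) or E14.5 WT replicate 7.2 (0.0772). Valve mesenchyme genes (0.14, 0.0256) lost it without E13.5 WT replicate 2 (0.0923), E13.5 KO replicate 5 (0.138), E14.5 KO replicate 4 (0.282) or E14.5 WT replicate 7.2 (0.151). Sarcomere genes (-0.05, 0.035) lost it without E13.5 WT replicate 2 (0.0863), E13.5 KO replicate 7 (0.288), E14.5 KO replicate 2 (0.132), E14.5 WT replicate 7 (0.100) or E14.5 KO replicate 4 (0.290). With an estimated correlation the adjusted p of these lists was 0.236 (endothelial-to-myocardial), 0.559 (immediate-early), 0.36 (liver), 0.483 (stress), 0.696 (valve) and 0.836 (sarcomere). Markers of lymphatic endothelium (7 members, median -0.19, adjusted p = 0.869), skeletal muscle (8, 0.12, 0.578) and neural crest and nerve (12, 0.05, 0.877) were not called. Of the pan-endothelial genes, Eng (0.30, 0.0193), Lyl1 (0.43, 0.027) and Tal1 (0.29, 0.0434) rose, with calls kept in 8, 3 and 2 of 12 fits with 1 library left out. Not called either were erythroid genes (21, median -0.07, mean 0.02, adjusted p = 0.869), whose median and mean differed in sign.

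**Figure D2:**
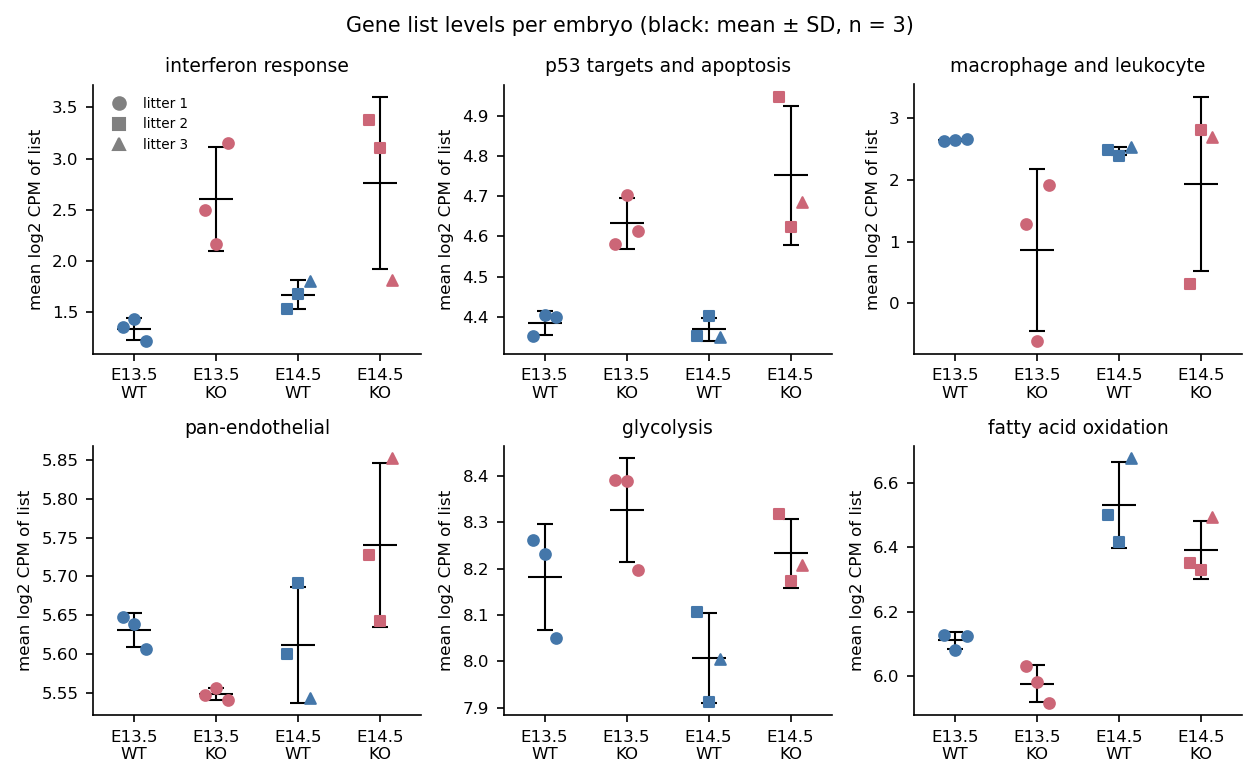
Mean log2 CPM of the genes of 6 lists in each embryo, WT in blue and KO in red, with marker shape for litter. Black marks show the mean ± SD of 3 embryos per group, and E13.5 KO replicate 5 and E14.5 KO replicate 2 lie lowest for macrophage genes.

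Where the changed genes lie was examined because Ino80 is on chromosome 2. Gchfr, a regulator of tetrahydrobiopterin synthesis that starts 0.205 Mb from Ino80 (chromosome 2, 119167773 to 119172390), fell by 1.80 ± 0.19 (adjusted p = 0.000683). Capn3, a calcium-dependent protease 1.08 Mb from Ino80 (chromosome 2, 120456019 to 120504913), fell from 6.52 to 2.53 CPM at E13.5 and from 8.32 to 2.66 CPM at E14.5 (averaged adjusted p = 0.000683). Both kept their calls without any 1 library. Within 20 Mb of Ino80, 27 of 359 tested genes changed in the averaged comparison (7.52%; 11 up, 16 down), against 260 of 19260 beyond 40 Mb or on other chromosomes (1.35%). The difference was tested by a two-sided Fisher's exact test (p = 3.70e-12), in which neighbouring genes are not independent replicates. The window was chosen after the values were seen.

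**Figure D3:**
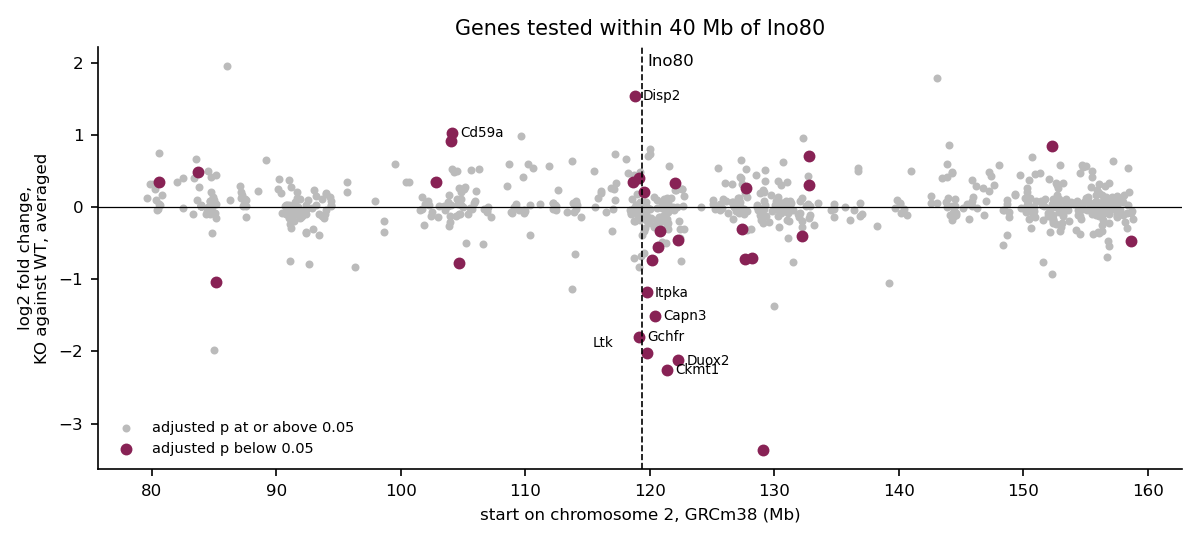
Averaged log2 fold change of KO over WT for tested genes within 40 Mb of Ino80, by gene start on chromosome 2 (Mb, GRCm38). Purple marks genes with an adjusted p below 0.05 and the dashed line marks Ino80, with the changed genes spread on both sides of it.

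At E13.5, the question was what differed at the earlier stage alone, 3 KO against 3 WT embryos of 1 litter. Tmem255a, a transmembrane protein gene (chromosome X, 38196573 to 38252439), fell by 1.36 ± 0.15 on the log2 scale (adjusted p = 0.00809), from 44.4 ± 6.05 to 17.3 ± 1.498 CPM. Pecam1 fell by 0.62 ± 0.08 (0.00809), from 143 ± 8.45 to 93.0 ± 2.09 CPM, and the endothelial transcription factor gene Sox7 by 0.47 ± 0.07 (0.0348), from 49.2 to 35.6 CPM. Ctla2a, a cysteine protease inhibitor gene (chromosome 13, 60934155 to 60936625), rose by 1.02 ± 0.13 (0.0133), from 25.3 ± 4.63 to 51.3 ± 3.33 CPM. The Wnt ligand gene Wnt9b, expressed in endocardium, rose by 1.63 ± 0.24 (0.0269), from 2.79 to 8.61 CPM.

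In all, 22 genes changed at E13.5, 18 down and 4 up (Ctla2a, Wnt9b, Eda2r and Nppc, the last named after its values were seen). All 22 separated the KO from the WT embryos without overlap, as did 19.6% of all genes, where chance gives 10%. Of the named genes, Tmem255a alone kept its call without any 1 library. Pecam1 lost it without E13.5 WT replicate 4 (0.0700) or KO replicate 3 (0.0509), and Ctla2a without E13.5 WT replicate 1 (0.0813), WT replicate 4 (0.0729), KO replicate 3 (0.0509) or KO replicate 7 (0.0747). Sox7 lost it without E13.5 WT replicates 1 (0.151) or 4 (0.147), or KO replicates 3 (0.135), 5 (0.158) or 7 (0.112), and Wnt9b without the same 5 libraries (0.127, 0.128, 0.0646, 0.100 and 0.115). The count was 4 without WT replicate 1, 2 without WT replicate 4, 4 without KO replicate 3, 6 without KO replicate 5 and 5 without KO replicate 7. It was 62, 45 and 69 without E14.5 KO replicate 2, 4 or 1, and 95 when the 6 E13.5 libraries were fitted alone. Without a low-count filter it was 40, and DESeq2 called 306. Sex was unbalanced at E13.5, where 1 of 3 WT and 2 of 3 KO embryos expressed Y-linked genes. With Y-linked expression as a covariate the count was 9, and Sox7 (0.0633), Eda2r (0.0633), Cpa3 (0.0633), Gchfr (0.0654) and Capn3 (0.0599) were not among them. With litter as a block it was 60, including all 22, and Cldn5 (-0.87, 0.0131 against 0.109), Aplnr (-1.16, 0.0217 against 0.0698), Bst2 (1.36, 0.0365 against 0.0749), Cxcr4 (-1.21, 0.0228 against 0.154), Mfng (-0.78, 0.0228 against 0.056), Isg15 (2.81, 0.0217 against 0.165) and Sema3g (-0.93, 0.0476 against 0.136) passed. All 6 E13.5 embryos are of 1 litter, so the block adjusted nothing between them. It changed these calls only through the spread that all groups share. Fixed-panel genes of endothelium (Tek -0.10, Cdh5 -0.14, Npr3 0.05, Nfatc1 -0.17, Apln -0.32) and myocardium (Hey2 -0.18, Nppa 0.46, Myh6 -0.25, Myh7 -0.11) did not pass. Nor did Wt1 (0.07), Vegfa (0.00), E2f1 (0.07), Cdkn1a (0.85) or Hbb-bs (-1.31).

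The groups called at E13.5 included interferon response genes (median 1.43, 17 of 18 above 0, camera adjusted p = 3.22e-16; adjusted p = 0.251 with an estimated correlation). None passed over all genes and 13 rose adjusted over the list alone. The interferon score was 1.33 ± 0.109 in WT and 2.60 ± 0.506 in KO embryos. Macrophage and leukocyte genes had a median of -1.52 with 17 of 18 below 0 (4.19e-12; adjusted p = 0.376 with an estimated correlation) and 0 members past the test. Csf1r, the receptor of the main macrophage growth factor, lay at 23.1 CPM in WT and 7.31 in KO (-1.64, adjusted p = 0.361). The macrophage score was 2.65 ± 0.0144 in WT and 0.861 ± 1.32 in KO, with KO replicate 5 at -0.617 (exact permutation p = 0.1, the smallest possible, two-sided). Coronary arterial endothelial genes had a median of -0.25 with 15 of 17 below 0 (6.69e-07; adjusted p = 0.251 with an estimated correlation). Notch signalling genes had a median of -0.18 with 12 of 16 below 0 (8.49e-05; adjusted p = 0.251 with an estimated correlation). Adjusted over the list alone, 6 arterial and 5 Notch genes fell, and over all genes 0 did. The p53 list had a median of 0.21 (1.48e-05; adjusted p = 0.309 with an estimated correlation), with Eda2r up over all genes (1.32 ± 0.21, 0.0465) against 5 up and 2 down adjusted over the list alone. Eda2r kept that call in 3 of 12 fits with 1 library left out (highest adjusted p 0.206). These 5 lists kept their calls without any 1 library.

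A further 8 of the 13 lists called at E13.5 (7 up, 6 down; 0 with an estimated correlation, smallest adjusted p 0.251) lost their calls without single libraries. Pan-endothelial genes (median -0.07, 0.0397) lost it without E13.5 WT replicate 1 (0.0833), WT replicate 4 (0.0604), KO replicate 3 (0.0874), KO replicate 7 (0.0825) or E14.5 KO replicate 2 (0.0506). With Y-linked expression as a covariate their median was -0.02 (0.264). Glycolysis (0.15, 0.00199) lost it without E13.5 WT replicate 2 (0.280) or KO replicate 3 (0.116), and hypoxia response (0.17, 0.00361) without WT replicate 2 (0.781), KO replicate 5 (0.147) or KO replicate 5 with E14.5 KO replicate 2 (0.0694). Immediate-early genes (0.10, 0.0265) lost it without WT replicate 1 (0.224), WT replicate 4 (0.0932), KO replicate 3 (0.0554) or KO replicate 7 (0.0593). Valve mesenchyme (0.15, 0.0164) lost it without WT replicate 2 (0.184), KO replicate 5 (0.275) or KO replicate 7 (0.0615). The venous list (-0.11, 0.0164) lost it without WT replicate 4 (0.0721) or KO replicate 3 (0.0554), or with Y-linked expression as a covariate (0.0557). Fatty acid oxidation (-0.10, 0.00155) lost it without KO replicate 7 (0.0825), and S-phase genes (0.08, 0.00217) without KO replicate 3 (0.123). With an estimated correlation the adjusted p was 0.309 for the venous list and 0.721 for the other 7. Without KO replicate 3, 8 lists were called.

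At E14.5, the same question was asked 1 day later, with embryos of litters 2 and 3. Ctla2a rose by 1.21 ± 0.13 on the log2 scale (adjusted p = 0.00404), from 24.2 ± 1.69 to 55.9 ± 9.02 CPM, and Eda2r by 1.86 ± 0.22 (0.00616), from 5.27 to 19.2 CPM. Ttc9 (chromosome 12, 81631249 to 81667557) rose by 1.09 ± 0.14 (0.00616), from 9.03 to 19.2 CPM, and Mlkl by 1.67 ± 0.23 (0.0105), from 2.23 to 7.11 CPM. AU021092 fell by 1.56 ± 0.20 (0.00737), from 3.67 to 1.24 CPM, and Cpa3 by 2.69 ± 0.38 (0.0123). Apob, the apolipoprotein of liver-made and yolk-sac-made lipoproteins (chromosome 12, 7977648 to 8016835), lay at 0.130 to 0.579 CPM in the WT embryos and had 0 counts in all 3 KO embryos. Against a floor of 3 counts per library it was at least 7.72-fold lower.

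In all, 46 genes changed at E14.5, 30 up and 16 down. All 46 separated the groups without overlap, as did 12.7% of all genes, where chance gives 10%. Ctla2a, Eda2r, Ttc9 and AU021092 kept their calls without any 1 library, but Ttc9 (0.0555) and AU021092 (0.0737) lost them without E13.5 KO replicate 5 and E14.5 KO replicate 2. Among the others, Mlkl lost it without WT replicate 7.2 (0.0726) and Cpa3 without KO replicate 2 (0.0706). Apob kept its call in 5 of 12 such fits (highest adjusted p 0.114). The count was 25 without E13.5 KO replicate 3, 13 without E14.5 KO replicate 2, 23 without WT replicate 7, 10 without WT replicate 7.2 and 107 without KO replicate 1. It was 10 without E13.5 KO replicate 5 and E14.5 KO replicate 2 and 77 without a low-count filter, and DESeq2 called 337. With the 6 E14.5 libraries fitted alone, 2 genes were called, Ctla2a among them; there the adjusted p was 0.14 for Eda2r, 0.131 for Ttc9 and 0.058 for AU021092. With litter as a block 92 genes were called, including all 46, and the named genes that then passed, with their blocked log2 fold changes, were Bst2 (1.31, 0.0357 against 0.0626), Eng (0.43, 0.0332 against 0.0533), Inhbb (1.28, 0.00527 against 0.0644), Lyl1 (0.53, 0.0497 against 0.11), Plvap (0.60, 0.00158 against 0.143), Tgfb1 (0.45, 0.0406 against 0.0614), Wt1 (0.49, 0.0309 against 0.0644) and Zmat3 (0.57, 0.0422 against 0.0699). Of the fixed panel, Tek (0.17), Pecam1 (-0.32, from 155 to 124 CPM), Cdh5 (0.12), Npr3 (0.31), Nfatc1 (0.21), Apln (0.18) and Hey2 (-0.09) did not pass. Nor did Nppa (0.72), Myh6 (-0.33), Myh7 (-0.26), Vegfa (0.28), Cdkn1a (0.79), E2f1 (-0.15) or Hbb-bs (0.28).

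Interferon response genes moved furthest as a group at E14.5 (median 1.40, 17 of 18 above 0, camera adjusted p = 3.12e-19; adjusted p = 0.174 with an estimated correlation), with 0 past the test over all genes and 16 up adjusted over the list alone. The interferon score was 1.67 ± 0.141 in WT and 2.76 ± 0.841 in KO embryos, and KO replicate 1 (1.81) lay level with its WT litter mate, replicate 7.2 (1.81). The p53 list had a median of 0.25 (18 of 20 above 0, 5.65e-14; adjusted p = 0.0602 with an estimated correlation), with 1 member up over all genes and 11 adjusted over the list alone. Hypoxia response (0.28, 4.06e-10) and glycolysis (0.21, 3.77e-08) rose as groups with 0 members past the test over all genes. Adjusted over the list alone 3 and 4 members rose, and adjusted p = 0.374 and 0.338 with an estimated correlation. Respiratory chain genes had a median of -0.16 with 0 of 29 above 0 (1.31e-08; adjusted p = 0.516 with an estimated correlation). Pan-endothelial genes had a median of 0.22 with 19 of 24 above 0 (1.51e-06; adjusted p = 0.338 with an estimated correlation), with 0 past the test over all genes and 12 up and 3 down adjusted over the list alone. Endothelial-to-myocardial signals had a median of 0.22 (0.000542; adjusted p = 0.0602 with an estimated correlation), with 0 past over all genes and 5 up and 1 down adjusted over the list alone. These 7 lists kept their calls without any 1 library, but with litter 3 left out the pan-endothelial (0.14) and endothelial-to-myocardial (0.0748) lists did not. The macrophage list was not called (-0.13, 0.227). Its scores were 2.81 and 2.70 in KO replicates 4 and 1, above all E14.5 WT embryos (highest 2.54), and 0.314 in KO replicate 2.

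The other 9 of the 16 lists called at E14.5 (11 up, 5 down; 0 with an estimated correlation, smallest adjusted p 0.0602) rested on single libraries. Fatty acid oxidation (median -0.15, 1.41e-05) lost its call without WT replicate 7.2 (0.0502) and sarcomere genes (-0.11, 0.00139) without KO replicate 4 (0.156). The liver list (-0.75, also with Apob at its bound; 0.0165) lost it without KO replicate 2 (0.134), WT replicate 7 (0.0536) or KO replicate 4 (0.101). Its median turned to 0.06 with only the 6 E14.5 libraries (0.602) and to 0.17 without E13.5 KO replicate 5 and E14.5 KO replicate 2 (0.223), so its direction was not stable. Immediate-early genes (0.14, 0.0184) lost their call without WT replicate 7 (0.143) or KO replicate 1 (0.475). Epicardial genes (0.10, 0.0209) lost it without KO replicate 2 (0.0895), WT replicate 7 (0.0811) or WT replicate 7.2 (0.0646). Endocardial genes (0.23, 0.0221) lost it without KO replicate 4 (0.523) or WT replicate 7.2 (0.715), and G2/M genes (0.08, 0.0231) without KO replicate 2 (0.481, where the median turned to -0.03) or WT replicate 7 (0.502). With E13.5 KO replicate 5 left out as well as E14.5 KO replicate 2, the G2/M median was also -0.03 (0.46). Stress response genes (0.05, 0.0279) lost it without KO replicate 2 (0.612), WT replicate 7 (0.0501) or WT replicate 7.2 (0.139). Ribosomal protein genes (-0.06, 0.0473) were no longer called with litter as a block (0.0631). Without 1 library they lost the call for all 6 E13.5 libraries (0.0507 to 0.0794), for WT replicate 7 (0.504) and for KO replicate 4 (0.738). With an estimated correlation these 9 lists had an adjusted p between 0.409 and 0.723.

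Whether the KO effect differed between the stages was tested directly. The KO effects had the same sign at both stages for most changed genes: 22 of the 22 E13.5 calls at E14.5, and 29 of the 30 rises and 16 of the 16 falls called at E14.5 at E13.5. The calls shared 2 rises and 9 falls, where chance gives 0.0058 and 0.0139, and the effects correlated across all genes with r = 0.36, although genes are not independent replicates. No gene passed: edgeR called 0 genes for the interaction, with 746 at an unadjusted p under 0.05, and DESeq2 called 2, Emp1 and Sepp1, named after their values were seen. Sox7 (0.41 ± 0.10) and Pecam1 (0.30 ± 0.11) both had an adjusted p of 0.997. As groups, pan-endothelial genes lay at a median of -0.07 at E13.5 and 0.22 at E14.5, and the difference had a median of 0.25 with 22 of 24 members above 0 (camera adjusted p = 8.90e-11; adjusted p = 0.237 with an estimated correlation). Macrophage and leukocyte genes lay at -1.52 and -0.13, with a difference of 1.34 (9.89e-08; adjusted p = 0.638 with an estimated correlation). The pan-endothelial list had 1 member past the test adjusted over the list alone, the macrophage list 0. Both kept their calls without any 1 library, whereas the other 12 of the 14 called lists lost them without at least 1, and without E14.5 WT replicate 7.2 only 6 were called. The interferon list did not differ detectably (-0.03, adjusted p = 0.881).

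How the heart changed from E13.5 to E14.5 was asked in each genotype, with stage confounded with litter. Cnn1, a smooth muscle actin-binding protein (chromosome 9, 22099216 to 22109630), fell by 0.62 ± 0.08 in WT (adjusted p = 0.00855), from 219 to 143 CPM, and by 0.62 ± 0.08 in KO (0.00333), from 279 to 181 CPM. Its list went the other way: the mural and smooth muscle score rose from 4.08 to 4.77 in WT and from 4.02 to 4.69 in KO. Camera called that list in both genotypes, but not with an estimated correlation. Each call was kept in 11 of 12 fits with 1 library left out. Rgs5, a pericyte marker (chromosome 1, 169655501 to 169695813), rose by 2.499 ± 0.31 in WT (0.015), from 13.3 to 74.9 CPM, and by 2.40 ± 0.31 in KO (0.00917), from 13.2 to 69.4 CPM. Acsl1, which activates fatty acids for oxidation (chromosome 8, 46471037 to 46536051), rose by 1.30 ± 0.21 in WT (0.022) and by 1.20 ± 0.21 in KO (0.0202). Casq2, the calcium store protein of the sarcoplasmic reticulum (chromosome 3, 102086415 to 102146514), rose by 1.32 ± 0.24 in WT (0.0267), from 326 to 811 CPM, and by 1.16 ± 0.24 in KO (0.0349). Tgfb2, a growth factor of valve formation, fell by 0.51 ± 0.10 in WT (0.0237) and by 0.54 ± 0.10 in KO (0.0171).

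In WT 836 genes changed with stage, 430 up and 406 down, and in KO 774, 437 up and 337 down. Both shared 158 rises and 130 falls, where chance gives 9.08 and 6.61, and the stage effects correlated across genes with r = 0.54, although genes are not independent replicates. Of the genes named for stage, Cnn1 kept its call in both genotypes without any 1 library. Rgs5 lost it in WT without E13.5 WT replicate 1 (0.0785) or 4 (0.0609) and in KO without E13.5 KO replicate 7 (0.0543). Acsl1 lost it in WT without E13.5 WT replicate 1 (0.0842), 4 (0.0663) or 2 (0.0578), and in KO without E13.5 KO replicate 3 (0.0604), 5 (0.0637) or 7 (0.0827) or E14.5 KO replicate 1 (0.0642). Tgfb2 lost it in WT without E13.5 WT replicate 1 (0.0934) or 4 (0.0730) or E14.5 WT replicate 7.2 (0.126), and in KO without E13.5 KO replicate 3 (0.0646) or 5 (0.0637) or E14.5 KO replicate 1 (0.0519). Casq2 lost it in WT without E13.5 WT replicate 1 (0.103), 4 (0.0680) or 2 (0.0658) or E14.5 WT replicate 7.2 (0.111). In KO it kept its call in 4 of 12 fits, with the highest adjusted p of 0.121 without E13.5 KO replicate 7. The WT count was 8, 29 and 123 without E13.5 WT replicates 1, 4 and 2, 554, 451 and 497 without E13.5 KO replicates 3, 5 and 7, and 22 without E14.5 WT replicate 7.2. The KO count was 414 without E13.5 WT replicate 4, 116, 141 and 66 without E13.5 KO replicates 3, 5 and 7, and 124 without E14.5 KO replicate 1. With litter as a block the counts were 299 in WT and 332 in KO, of which 276 and 311 were among the genes called without it. The blocked comparison sets litter 2 against litter 1, so it does not separate stage from litter.

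Fatty acid oxidation genes rose with stage in both genotypes. In WT their median was 0.38 with 25 of 26 above 0 (camera adjusted p = 9.93e-18; adjusted p = 0.313 with an estimated correlation), and 13 rose over all genes and 21 adjusted over the list alone. In KO it was 0.36 with 26 of 26 above 0 (5.38e-17; adjusted p = 0.259 with an estimated correlation), with 11 and 18. Respiratory chain genes rose by a median of 0.30 in WT (29 of 29 above 0, 5.12e-16; adjusted p = 0.313 with an estimated correlation), 8 of them over all genes and 26 adjusted over the list alone. In KO the median was 0.15 (29 of 29, 4.94e-06; adjusted p = 0.451 with an estimated correlation), with 1 and 4. Valve mesenchyme genes fell, with a median of -0.38 in WT (6.27e-05; adjusted p = 0.313 with an estimated correlation; 3 down over all genes) and -0.56 in KO (1.74e-07; adjusted p = 0.348 with an estimated correlation; 5 down over all genes). Adjusted over the list alone, 8 valve genes fell in WT and 9 in KO, and 1 rose in each. Endocardial genes had a median of -0.44 in WT (2.88e-06; adjusted p = 0.313 with an estimated correlation), with 4 down over all genes and 9 down and 1 up adjusted over the list alone, and of -0.27 in KO (0.00552; adjusted p = 0.451 with an estimated correlation), with 0 and 1 down. These lists kept their calls in both genotypes without any 1 library, but with E13.5 KO replicate 5 and E14.5 KO replicate 2 both left out the endocardial list lost its KO call (-0.17, 0.148).

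Other lists held without any 1 library in 1 genotype alone, which does not show that the genotypes differ. In WT sarcomere genes rose (median 0.22, 0.000379; adjusted p = 0.491 with an estimated correlation), while trabecular (-0.31, 0.00665), compact myocardial (-0.21, 0.0144) and epicardial genes (-0.19, 0.00958) fell (adjusted p = 0.313 with an estimated correlation for each). In KO S-phase genes fell (-0.16, 3.99e-07; adjusted p = 0.431 with an estimated correlation), 8 of 28 over all genes and 13 adjusted over the list alone. Notch signalling genes rose in KO (0.34, 4.06e-06; adjusted p = 0.235 with an estimated correlation), 7 of 16 over all genes, against 8 up and 1 down adjusted over the list alone. Pan-endothelial genes (0.24, 1.07e-05) and coronary capillary genes (0.30, 2.66e-05) also rose in KO (adjusted p = 0.348 with an estimated correlation for each). In all, 16 lists were called in WT (6 up, 10 down) and 13 in KO (9 up, 4 down), and 0 in either with an estimated correlation (smallest adjusted p 0.313 and 0.235). With litter as a block, S-phase (0.201 against 0.0394), lung and foregut (0.0719 against 0.0265) and retinoic acid lists (0.0545 against 0.0263) lost their calls in WT and compact myocardium (0.0610 against 0.0355) in KO. Those WT lists also lost them without single libraries. S-phase genes did so without E13.5 WT replicate 4 (0.0611) or 2 (0.0750), E14.5 KO replicate 2 (0.0511), or E14.5 WT replicate 7 (0.101) or 7.2 (0.136), and the retinoic acid list without E13.5 WT replicate 4 (0.0579) or E14.5 WT replicate 7 (0.0600) or 7.2 (0.0761). Lung and foregut genes did so without E13.5 WT replicate 4 (0.0611) or 2 (0.119), E13.5 KO replicate 5 (0.0890), E14.5 WT replicate 8 (0.164), 7 (0.0530) or 7.2 (0.269), or E14.5 KO replicate 2 (0.119), and their median turned from -0.73 to 0.17 without a low-count filter (0.604). Compact myocardium lost its KO call without E13.5 KO replicate 5 (0.0776) or E14.5 KO replicate 2 (0.0620).

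**Figure D4:**
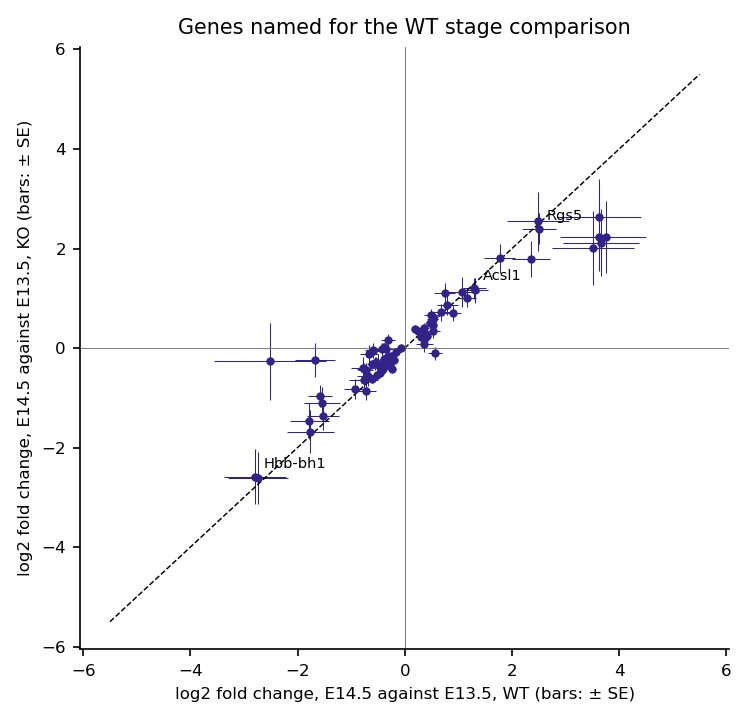
Stage effect (log2 fold change of E14.5 over E13.5) in WT on the x axis and in KO on the y axis for the genes named for the WT comparison. Bars are ± SE of the edgeR fit with 3 embryos per group, and the dashed line marks equal effects.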

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

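For 14 gene lists camera called the KO effect at E14.5 different from that at E13.5 in a test of the difference itself. With genotype labels exchanged within stages, 23 of 100 splits, the real one among them, called as many lists (highest other 20). Random grouping is therefore not excluded for this number of lists. The tests of the 3 patterns weighed here were chosen after the results were seen. The median difference was 0.25 for pan-endothelial genes (camera adjusted p = 8.90e-11) and 1.34 for macrophage and leukocyte genes (9.89e-08), and both calls held without any 1 library. None of the 14 calls held with an estimated correlation, where the adjusted p lay between 0.237 and 0.72. The other 12 lists each lost the call without at least 1 library. With Y-linked expression as a covariate, hypoxia response (median 0.03, 0.364), p53 (0.107), endocardial (0.0875) and endothelial-to-myocardial (0.068) genes lost it. Without litter 3 the Notch (0.726), coronary arterial (0.446), coronary capillary (0.44), endocardial (0.207), venous (0.166) and endothelial-to-myocardial (0.137) lists did, and without E13.5 KO replicate 5 and E14.5 KO replicate 2 the p53 (0.465), sarcomere (0.367), hypoxia (0.139) and venous (0.0595) lists did. Respiratory chain genes (-0.13, 2.5e-05) lost it without E14.5 KO replicate 4 (0.0563) or E14.5 WT replicate 7.2 (0.0574). S-phase genes (-0.12, 0.00214) lost it without E13.5 KO replicate 3 (0.0813), E14.5 WT replicate 8 (0.0709) or E14.5 KO replicate 1 (0.0829). Coronary arterial genes (0.14, 0.00421) lost it without E14.5 WT replicate 7.2 (0.0574) or E14.5 KO replicate 1 (0.0742), and coronary capillary genes (0.20, 0.00633) without E14.5 KO replicate 1 (0.156). Venous genes (0.14, 0.00889) lost it without E14.5 WT replicate 7.2 (0.0902), and endothelial-to-myocardial signals (0.18, 0.0142) without E13.5 KO replicate 3 (0.0553) or E14.5 WT replicate 7.2 (0.0916). Notch signalling genes (0.10, 0.0143) lost it without E14.5 WT replicate 7.2 (0.0721) or E14.5 KO replicate 1 (0.196). Hypoxia response genes (0.11, 0.0143) lost it without E13.5 WT replicate 1 (0.386) or 4 (0.0584), E13.5 KO replicate 3 (0.0913) or 7 (0.131), E14.5 KO replicate 2 (0.759) or E14.5 WT replicate 7 (0.217). Endocardial genes (0.18, 0.0177) lost it without E13.5 WT replicate 1 (0.0553), E13.5 KO replicate 3 (0.131), E14.5 KO replicate 4 (0.298) or E14.5 WT replicate 7.2 (0.653). The p53 list (0.11, 0.0199) lost it without E13.5 KO replicate 3 (0.0813) or 7 (0.0611), E14.5 KO replicate 2 (0.767) or E14.5 WT replicate 7.2 (0.0574). Sarcomere genes (-0.12, 0.0202) lost it without E13.5 KO replicate 3 (0.525), E14.5 KO replicate 2 (0.319) or 4 (0.353), or E14.5 WT replicate 7 (0.200) or 7.2 (0.0574). Ribosomal protein genes (-0.0726, 0.0372) lost it without E13.5 WT replicate 1 (0.386) or 4 (0.0718), E13.5 KO replicate 3 (0.211) or 5 (0.0647), E14.5 WT replicate 7 (0.507) or E14.5 KO replicate 4 (0.525).

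Genes changed in KO hearts crowd around Ino80 on chromosome 2: 8 of 55 within 1 Mb, 7 of 68 from 1 to 5 Mb, 12 of 236 from 5 to 20 Mb and 5 of 386 from 20 to 40 Mb. Action of the altered locus on its near neighbours alone is argued against by the share from 5 to 20 Mb, 5.08% against 1.35% elsewhere (two-sided Fisher's exact test, p = 0.000126). Random grouping of the embryos is argued against by the splits. With the 293 top genes of each split, 1 of 100 splits, the real one, had as many of them within 20 Mb (27, highest other 16). In the real split, of 18324 windows centred on genes of other chromosomes 0 reached the 7.52% around Ino80 (highest 6.06%). These windows overlap heavily, and they do not bear on how the embryos were grouped. A candidate explanation is a haplotype of another strain carried along with the targeted allele, which predicts the excess from 5 to 20 Mb, but neither strain nor breeding is given in the sources used here. An effect of Ino80 loss on this region stays open as untested, and genes there that are past the threshold, such as Ltk (-2.02), Duox2 (-2.12) and Tcp11l1 (-0.78), named after their values were seen, may reflect either.

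Interferon response genes were higher in KO hearts, with a median of 1.41. Of 100 splits 1, the real one, gave a median as high (highest other 1.20). The list was singled out after it moved furthest under the real labels, and the other splits were read for this list alone. That favours the real split, so this share does not decide against random grouping. More leukocytes in the tissue are argued against at E13.5 by the macrophage and leukocyte list (averaged median -0.85). Its E13.5 median was -1.52 (camera adjusted p = 4.19e-12, and 0.376 with an estimated correlation). This explanation stays open at E14.5, where the list was not called (-0.13, 0.227). There KO replicates 4 (2.81) and 1 (2.70) lay above all E14.5 WT hearts (highest 2.54). Exposure of a whole litter is argued against in litter 1, where the lowest KO score exceeds the highest WT score by 0.74. A single aberrant library is argued against by the calls without each KO library in turn (highest adjusted p 1.02e-18), although with all libraries the call ends with an estimated correlation (0.146). Also open is a response of the disrupted cells themselves, as a hypothesis that whole-heart counts cannot place in a cell type, and E14.5 KO replicate 1 (1.81) did not exceed its WT litter mate (1.81).

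Embryonic globins made up 32.6 ± 6.16% of globin counts in E13.5 KO and 13.4 ± 3.12% in E13.5 WT hearts (two-sided exact permutation p = 0.1, the smallest possible), and 8.65 ± 10.5% against 1.37 ± 1.41% at E14.5 (p = 0.4), where each KO embryo exceeded the WT embryos of its own litter (exact permutation within litters p = 0.167, the smallest possible). A different amount of blood is argued against, since at E13.5 embryonic globins lay at 1.04 ± 0.205 and adult globins at -0.62 ± 0.402. The difference was 1.66 (SE 0.451) in log2 fold change, with an SE that treats the sums as independent although the same embryos gave both. The adult fall lay in Hbb-bs (-1.31) and Hbb-bt (-1.32), with Hba-a1 at -0.20 and Hba-a2 at -0.21, and no single globin gene passed. Reads of near-identical globin copies are also assigned uncertainly. A delay of the whole heart may contribute: over all genes, KO and stage effects correlated with r = -0.06, and 24 of 100 splits were as low (lowest other -0.25), but most of those genes did not change with stage. On the 3557 genes that did, the KO minus WT position was -0.165 on a scale where the stages lie 1 apart. There 4 of 100 splits were as early (lowest other -0.205), and of 240 assignments within litters 1, the real one, was as early (next -0.153). For the correlation 14 of the 62 splits balanced by litter were as low. These counts are one-sided. The 3557 genes were chosen in the fit of the real groups, which can favour the real split, so the counts of positions do not decide for a delay. At a constant rate per day, which was not tested, the globin ratio was shifted by 0.407 days at E13.5 and 0.52 at E14.5, more than the stage genes (-0.154 and -0.176), so a delay as the whole or a part of the cause and a direct effect on blood cells, which also arise from Tie2-expressing precursors, cannot be told apart.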

How the results depend on the processing

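Leaving out litter 3, and leaving out E13.5 KO replicate 5 with E14.5 KO replicate 2, were chosen after the data were seen; the other alternatives were planned. The medians of 3 called lists changed sign, each with the call lost, and the cause was not tested. For liver at E14.5 it was 0.0554 with only the compared libraries (0.602) and 0.17 without E13.5 KO replicate 5 and E14.5 KO replicate 2 (0.223). For G2/M at E14.5 it was -0.0283 without that pair (0.46) and ran from -0.028 without E14.5 KO replicate 2 (0.481) to 0.122 without KO replicate 1. For lung and foregut it was 0.17 for stage in WT without a low-count filter (0.604). Counts of genes changed are given in the order E13.5, E14.5, averaged, interaction, stage in WT and stage in KO, and where an alternative moved a count by over 1.5 times the cause was not tested unless stated. DESeq2 called 306, 337, 933, 2, 2129 and 1832 genes, which included 22, 46, 284, 0, 823 and 755 of those called by edgeR. Without a low-count filter 40 genes were called at E13.5 and 77 at E14.5, and 20 lists for stage in KO. With litter as a block the counts were 60 at E13.5, 92 at E14.5, 299 for stage in WT and 332 for stage in KO, and apart from the genes and lists named with a blocked value, 23 named genes in WT and 12 in KO lost their stage calls, 1 in each gained one and Tgfb2 gained an averaged call (0.27, 0.0357); it changed no other call. The block does not adjust the E13.5 embryos, all of litter 1, so the E13.5 count moved through the spread shared by all groups. For stage it sets litter 2 against litter 1 and does not control for litter. A Y-linked covariate gave 9 at E13.5 and 396 for stage in KO. Only the compared libraries gave 95 at E13.5, 2 at E14.5 and 289 for stage in KO; with 4 residual degrees of freedom, fewer samples set the spread. Without litter 3 the counts were 71 at E13.5 and 95 for stage in WT. Without E13.5 KO replicate 5 and E14.5 KO replicate 2 they were 10 at E14.5, 63 averaged (60 of them among the 293), 474 for stage in WT and 130 for stage in KO.

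Leaving out 1 library gave 2 to 69 genes at E13.5, 10 to 107 at E14.5, 125 to 483 averaged, 0 to 0 for the interaction, 8 to 1081 for stage in WT and 66 to 1076 for stage in KO. The lists called numbered 8 to 13, 11 to 22, 11 to 19, 6 to 15, 11 to 19 and 13 to 17. With an estimated correlation 0 lists were called in each of the 6 comparisons, and fry called 0, 2, 5, 0, 3 and 8. Of the named genes' results, 4130 kept their direction and their side of the threshold with 1 library left out, 677 lost a call, 70 gained one and 31 changed direction without a call. With RLE size factors 406 kept both and 3 lost a call, and no count moved by over 1.5 times. DESeq2 was run for genes alone, and fits of only the compared libraries for the comparisons within a stage or genotype. Depth limits the genes near 1 CPM and below, such as Apob, and at 1.5-fold the simulated interaction test recovered 29.9% of changed genes.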

Other observations

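Beside Cpa3, 6 further genes known from mast cells were looked up, and they did not move in 1 direction; they were chosen after their values were seen and were not tested as a list, whereas the counts of splits were planned before. In the averaged comparison the mast cell chymase gene Cma1 fell by 1.70 (edgeR adjusted p = 0.0347) and the interleukin-33 receptor gene Il1rl1 by 1.15 (0.0259), although neither passed at E13.5 (0.445 and 0.184) or E14.5 (0.0965 and 0.305) alone. The mast cell tryptase gene Tpsb2 did not pass averaged (0.108) or at E13.5 (0.597), but did at E14.5 (0.0265), with 1.17 CPM in WT and 0.0205 CPM in KO hearts. Kit, the stem cell factor receptor of mast cells and of other cell types, instead rose by 0.45 averaged (0.0164). The histamine-synthesis gene Hdc (0.32, 0.42) and the transcription factor gene Gata2 (0.13, 0.399) did not pass. Apart from these genes, C130074G19Rik (chromosome 1, 184871926 to 184883218), which the naming rule left out for its symbol, fell by 0.94 ± 0.0581 with an adjusted p of 7.63e-06.

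Splits of the embryos into other groups of the same sizes were counted for each comparison. For genes averaged over the stages, 1 of 100 splits gave as many calls, the real one with 293 (highest other 24). This argues against random grouping at that level but does not exclude it. A share of 1 in 100 is the smallest that these splits can give, and not all of them were balanced by litter. Splits that mix the genotypes also put a genotype difference into their spread, which lowers their counts. For the interaction all 100 gave as many as the real 0, and the highest other, 293, exchanges the genotype labels at E14.5. For lists, chance is not excluded averaged over the stages (10 of 100 gave as many; real 15, highest other 18) or for the interaction (23 of 100; real 14, highest other 20). In each comparison of 3 against 3 embryos the 10 splits are too few for a share under 0.05. For genes, the real count and the highest other were 22 and 416 at E13.5 (2 splits as high), 46 and 8 at E14.5 (1), 836 and 0 for stage in WT (1), and 774 and 1 for stage in KO (1). For lists they were 13 and 11 at E13.5 (1), 16 and 19 at E14.5 (4), 16 and 16 for stage in WT (2), and 13 and 16 for stage in KO (6). The split with 416 genes sets E13.5 WT replicates 1 and 4 and KO replicate 3 against WT replicate 2 and KO replicates 5 and 7, which points to a structure of the samples that follows the first principal component and is shared by both genotypes.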
